A study of Mus musculus with 50 samples.

How the data were processed

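RNA from frontal cortex synaptosomes, the pinched-off nerve terminals that brain fractionation yields, was measured on Illumina MouseRef-8 v2.0 BeadChips, 1 array per mouse. The 50 mice were on a CD1 background, aged 17 to 21 days, and wild type or constitutive Sod2 knockout (KO). Sod2 encodes the superoxide dismutase of the mitochondrial matrix. Per the labels, 200 ng of RNA was amplified in 1 round and labelled with biotin.

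The deposited probe table holds scanner signal intensity that the authors did not normalize, with no detection p-values and no control probes. The authors also deposited a table of log2 values normalized by a method that is not stated; that these are log2 values was read from the numbers themselves. Every column of the authors' log2 table ranked probes as the raw signal of the same array did, with Spearman rho from 0.9992 to 1.0000, and its column medians lay between 6.02 and 6.03. The raw signals were used for all results, and the authors' log2 values served as an alternative.

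A background correction from control probes or detection p-values had been planned first and could not be used. The planned fallback was applied instead: limma 3.58.1 in R 4.3.3, normexp background correction with an offset of 50, and quantile normalization of the log2 signals. Such an offset tends to shrink log2 changes, most for dim probes. Fold changes and counts over 2-fold are therefore likely to be too low. Of 25697 probes, the 15418 above the 40th percentile of mean log2 signal (6.01) were kept. Symbols were updated through the probe definitions and the reference gene table: 17548 probes had a current symbol, 1319 were renamed from their definition, 5842 through a synonym, and 988 kept the symbol of the file. For each of 11510 genes the probe with the highest mean signal was used. Array medians of raw signal ranged from 54.1 to 78.0.

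Groups came from the genotype and treatment labels. The replicate numbers run on over all 5 groups without repeats, so no samples were paired. A linear model with 1 mean per group was fitted to all 50 arrays with limma (lmFit, eBayes), and 10 contrasts were tested, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given with a log2 change are the standard errors of the limma contrast. They pool the spread of a gene over all groups and are too small where a compared group varied more. The model was tested on simulated data with 200 changed genes, where it recovered 70.1% of changes of 0.25 log2 and 95.5% of changes of 0.5 log2 in the low-dose genotype contrast, with 9 false calls. Each simulated gene varied independently of the others, with the same spread in all groups, so these figures need not carry over to the real arrays.

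The 37 gene lists were fixed before the data were examined. Lists with at least 3 measured members were tested with camera (preset inter-gene correlation 0.01), adjusted over lists within a contrast; camera with an estimated correlation and fry were alternatives. An adjusted p for a list is from camera with the preset value unless said otherwise. Marker means of 8 lists were compared between groups over 5 contrasts by permutation, exact where a group had 9 mice and with 100000 draws otherwise, and adjusted over these 40 comparisons. The size of the genotype change at both doses was compared over genes called in the averaged genotype contrast, with 10000 permutations of the dose labels within each genotype.

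Named genes followed a rule fixed before the data were examined. In the 2 genotype contrasts and in the dose contrast within KO these were Sod2, the 8 highest and 8 lowest changes past the threshold, and up to 4 changed members per list in order of the list test, to about 20 to 30 genes; the exact limit of 30 was set later. In other contrasts the 5 highest and 5 lowest were named, or the 3 with the smallest p where fewer than 3 passed. Transcripts with only a clone or locus identifier were skipped, and some genes that the rule names are not reported here.

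Also run, as laid down before the data were examined, were the authors' log2 values, no background correction (offset 16), no filter, the chip as a fixed or random block, array weights, a variance trend with robust fitting, every kept probe, a sex-linked covariate, and a fit of only the groups compared. A stricter detection filter could not be run, and a 70th percentile filter (log2 signal 6.43) took its place. That filter, leaving out each array in turn, leaving out the chip with only 2 arrays, and marker means of 4 cell types as covariates were chosen after seeing the data.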

Results

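The series covers 5 groups of mice: 10 Sod2 KO and 11 wild type at the low dose (1 mg/kg), 10 Sod2 KO and 10 wild type at the high dose (30 mg/kg), and 9 untreated wild type. No untreated Sod2 KO group is among the samples, so each KO value is from a treated mouse. The sample titles name the compound EUK8 and the treatment field names it EUK189; both are salen-manganese complexes that mimic superoxide dismutase and catalase, and the labels do not settle which was given. The question the labels imply is how loss of mitochondrial superoxide dismutase changed synaptic RNA, and how far the antioxidant dose altered that change. The arrays lay on 7 chips, 6 of which held all 5 groups, and raw bead signals ranged from 31.1 to 35672. The mean correlation of each array with the others of its group was 0.964 to 0.988.

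Sod2 RNA was not lower in mice labelled Sod2 KO. The single Sod2 probe gave a log2 signal of 10.23 ± 0.29 (SD, n = 10) in KO and 9.86 ± 0.19 (n = 11) in wild type at the low dose, a change of 0.37 ± 0.088 with adjusted p 0.00163. At the high dose the values were 10.13 ± 0.20 (n = 10) and 9.91 ± 0.20 (n = 10), a difference of 0.22 ± 0.09 with adjusted p 0.324. Untreated wild type had 9.72 ± 0.089 (n = 9). The labels do not say which part of the gene was deleted, so this probe gives no check of the genotype labels.

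**Figure D1:**
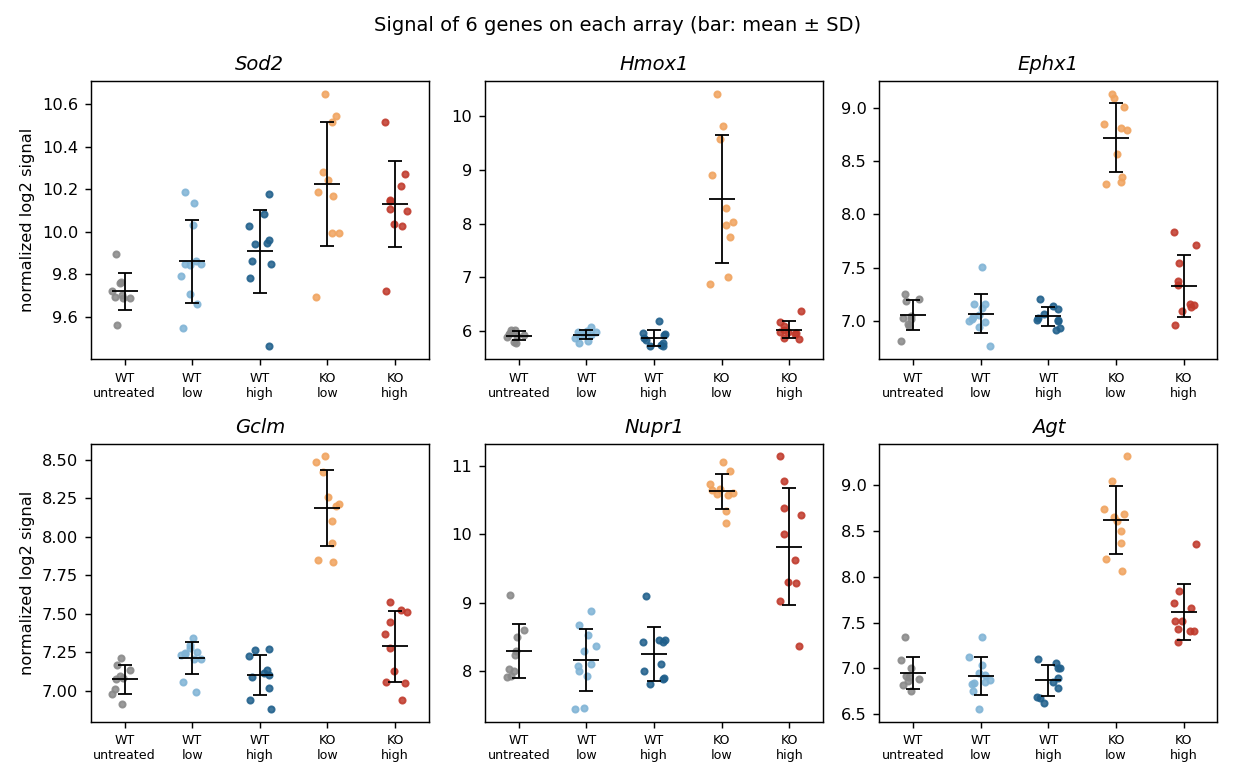
Normalized log2 signal of 6 genes on each of the 50 arrays by group, with bars for mean and SD. Hmox1, Ephx1 and Gclm were high in the low-dose Sod2 KO group, where Hmox1 had 8.46 ± 1.19 against 5.93 ± 0.086 in low-dose wild type and 6.03 ± 0.15 in high-dose Sod2 KO; Nupr1 and Agt were raised at both doses.

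At the low dose, Sod2 KO synaptosomes had far more RNA for stress response and detoxification genes than wild type. Hmox1, the inducible haem oxygenase, was at least 5.76-fold higher (log2 2.53 ± 0.23), and Nupr1, a stress-induced nuclear protein, was 5.53-fold higher (log2 2.47 ± 0.22). RNAs for fatty acid oxidation, the TCA cycle and antioxidant enzymes rose with them, while Arc, an activity-induced synaptic gene, was 3.05-fold lower (log2 -1.61 ± 0.30). The Hmox1 signal lay at the limit for dim probes (log2 6.01) in every group but low-dose KO. Its differences from low-dose KO, here and below, are thus lower bounds, apart from sampling error. On single arrays Hmox1 ran from 6.88 to 10.41 in low-dose KO and from 5.78 to 6.09 in low-dose wild type. The limma error pools the spread of all groups, so it is too small for Hmox1 changes that involve low-dose KO, here and below. Of 11510 genes, 2307 changed, 1112 higher and 1195 lower in KO, and 32 of these by more than 2-fold.

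Targets of ATF4, the transcription factor of the integrated stress response, formed one large group of higher genes at the low dose. Of 29 measured, 20 rose and 0 fell over all genes tested (21 and 0 adjusted over the list alone), with a mean log2 change of 0.47 and adjusted p 1.38e-14. Besides Nupr1, the transcription factor Atf5 changed by 1.74 ± 0.17, the amino acid transporter Slc7a5 by 1.43 ± 0.14, and the translation repressor Eif4ebp1 by 0.90 ± 0.12. Of 23 targets of NRF2, the regulator of detoxification genes, 14 rose and 0 fell (15 and 1 adjusted over the list alone; mean 0.48, adjusted p 5.22e-12). The epoxide hydrolase Ephx1 changed by 1.65 ± 0.10 and the glutathione transferase Gstm1 by 1.47 ± 0.16; a second, dimmer Gstm1 probe gave 0.13. Gclm, a subunit of the enzyme that starts glutathione synthesis, changed by 0.97 ± 0.074. Of 21 antioxidant enzymes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; mean 0.24, adjusted p 1.25e-05), with catalase (Cat) at 0.79 ± 0.12. With an estimated correlation the adjusted p was 0.000948 for the ATF4 list, 0.000948 for the NRF2 list and 0.0204 for the antioxidant list. Within each of the 6 chips with both groups, the ATF4 list mean was higher in KO, between 0.32 and 0.57, and so was the NRF2 list mean, between 0.39 and 0.62.

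Genes of mitochondrial fuel use were also higher at the low dose. Of 20 genes of fatty acid oxidation and ketone use, 15 rose and 0 fell (16 and 0 adjusted over the list alone; mean 0.51, adjusted p 2.21e-14). The long-chain acyl-CoA dehydrogenase Acadl changed by 0.99 ± 0.11, the thiolase Acaa2 by 0.94 ± 0.14, and the lipase inhibitor Angptl4 by 0.81 ± 0.14. Of 18 TCA cycle genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; mean 0.31, adjusted p 6.18e-08). Isocitrate dehydrogenases Idh2 and Idh3g changed by 0.90 ± 0.20 and 0.47 ± 0.064, the succinate dehydrogenase subunit Sdhb by 0.70 ± 0.075, and citrate synthase (Cs) by 0.65 ± 0.10. Of 13 mitochondrial chaperones and proteases, 5 rose and 0 fell (5 and 0 adjusted over the list alone; mean 0.25, adjusted p 0.000137). With an estimated correlation the adjusted p was 0.00304 for fatty acid oxidation, 0.0361 for the TCA cycle and 0.0204 for mitochondrial chaperones. Complex I had 8 of 34 higher and 0 lower (8 and 1 adjusted over the list alone), with adjusted p 0.00279, and adjusted p = 0.428 with an estimated correlation. Complexes II, III and IV had 6 of 22 higher and 1 lower (7 and 3 adjusted over the list alone), with adjusted p 0.0347, and adjusted p = 0.428 with an estimated correlation. ATP synthase had 6 of 16 higher and 0 lower (6 and 0 adjusted over the list alone), with adjusted p 0.0108, and adjusted p = 0.319 with an estimated correlation. The means of these 3 lists were 0.11, 0.11 and 0.15, and without low-dose KO replicate 30 they were 0.19, 0.17 and 0.20.

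Several genes outside these groups had some of the largest changes at the low dose. Cdo1, which breaks down cysteine, changed by 1.73 ± 0.13, angiotensinogen (Agt) by 1.70 ± 0.11, the methionine adenosyltransferase Mat2a by 1.64 ± 0.14, and the cold-inducible RNA-binding protein Rbm3 by 1.61 ± 0.13. Igfbp5, which binds insulin-like growth factors, changed by -1.50 ± 0.18, Pdzph1 by -1.35 ± 0.12, the calcium release channel Itpr1 by -1.06 ± 0.14, and the microglial receptor Fcrls by -1.05 ± 0.15. Dimmer probes of the same genes gave smaller changes for Mat2a (1.16, 0.76 and 0.78), Acadl (0.56) and Acaa2 (0.55 for the dimmest), and 0.061 for the dimmest of 3 Sdhb probes. Igdcc4 changed by -0.94 ± 0.10, the spine protein Sipa1l1 by -0.94 ± 0.12 and Prr18 by -0.90 ± 0.16.

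Synaptic and neuronal genes were lower in Sod2 KO at the low dose, with less certainty. Of 32 synaptic vesicle and release genes, 0 rose and 11 fell (0 and 13 adjusted over the list alone; mean -0.24, adjusted p 0.000118), and adjusted p = 0.21 with an estimated correlation. Of 25 postsynaptic density and glutamate receptor genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone; adjusted p 0.00155, and adjusted p = 0.254 with an estimated correlation). Of 20 neuron markers, 0 rose and 7 fell (0 and 8 adjusted over the list alone; adjusted p 0.00668, and adjusted p = 0.319 with an estimated correlation). Of 23 immediate early genes, 1 rose and 7 fell, Arc among them (1 and 7 adjusted over the list alone; adjusted p 0.00467, and adjusted p = 0.254 with an estimated correlation). The synaptic vesicle mean differed by -0.24 ± 0.093 (SE) between the groups, permutation p 0.019 and adjusted p 0.111, which did not pass. The neuron marker mean differed by -0.20 ± 0.10, permutation p 0.063 and adjusted p 0.18, and the microglia marker mean by -0.18 ± 0.10, permutation p 0.098 and adjusted p 0.231. Within the 6 chips, the synaptic vesicle mean was lower in KO on 5, with differences between -0.53 and 0.031.

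**Figure D2:**
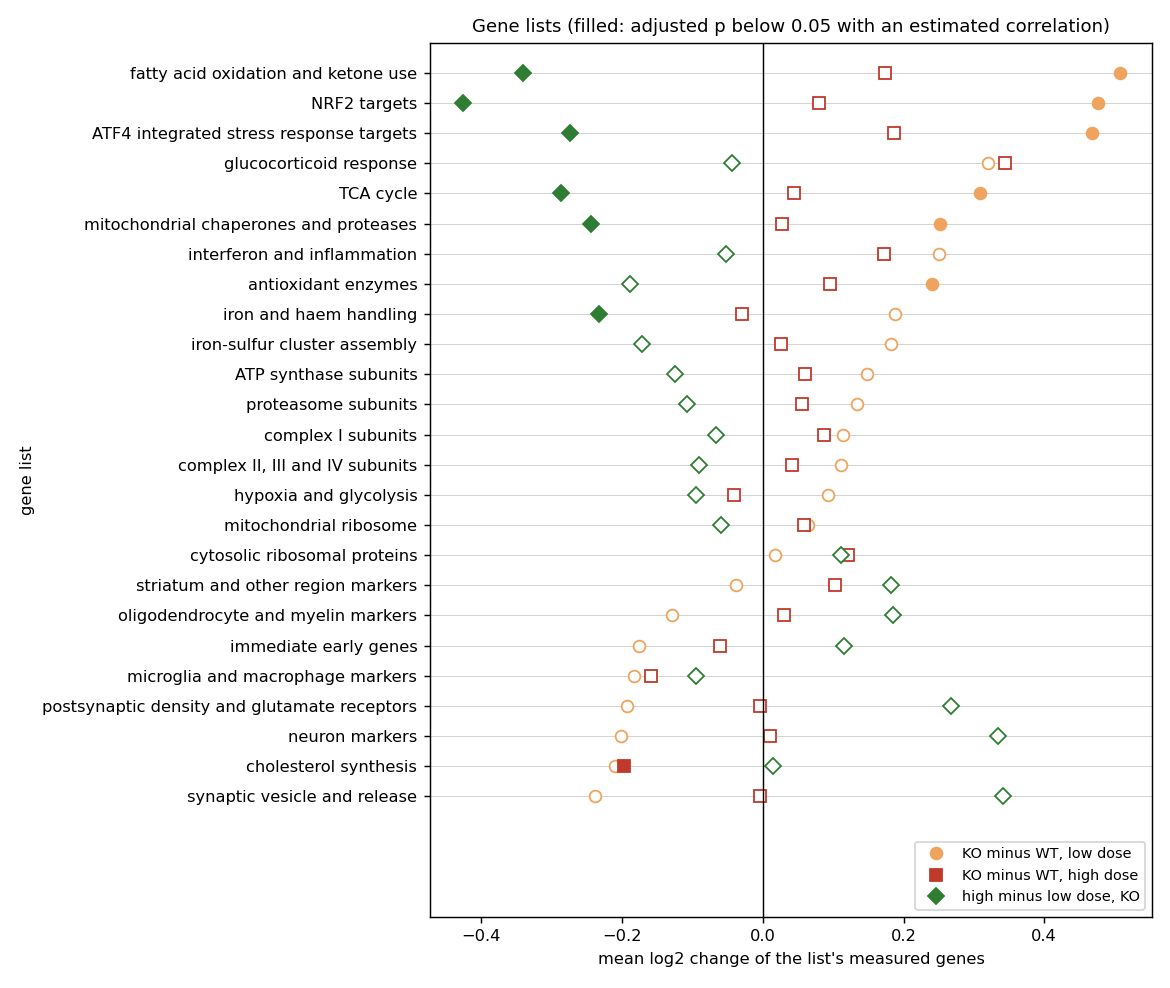
Mean log2 change of the measured genes of each list (horizontal axis) in 3 contrasts, for lists that passed in at least 1 of them; filled symbols also passed with an estimated correlation. The ATF4 list lies at 0.47 at the low dose, 0.19 at the high dose and -0.27 for high against low dose in KO.

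The remaining lists gave the following values at the low dose, in genes higher and lower, with the counts adjusted over the list alone in parentheses. Interferon and inflammation had 12 and 0 of 24 (12 and 0; adjusted p 0.000189), and adjusted p = 0.196 with an estimated correlation. The glucocorticoid response had 7 and 0 of 17 (9 and 0; adjusted p 0.00161), and adjusted p = 0.319 with an estimated correlation. Proteasome subunits had 11 and 0 of 27 (13 and 0; adjusted p 0.000589), and adjusted p = 0.138 with an estimated correlation. Cholesterol synthesis had 1 and 7 of 18 (1 and 7; adjusted p 0.00161), and adjusted p = 0.065 with an estimated correlation. Microglia markers had 0 and 6 of 20 (0 and 7; adjusted p 0.0113), and adjusted p = 0.428 with an estimated correlation. The mitochondrial ribosome had 14 and 3 of 68 (16 and 3; adjusted p 0.00457), and adjusted p = 0.428 with an estimated correlation. Iron-sulfur cluster assembly had 3 and 2 of 10 (4 and 2; adjusted p 0.0246), and adjusted p = 0.138 with an estimated correlation. Iron and haem handling had 7 and 2 of 21 (7 and 3; adjusted p 0.0184), and adjusted p = 0.138 with an estimated correlation. Hypoxia and glycolysis had 7 and 3 of 22 (7 and 3; adjusted p 0.0353), and adjusted p = 0.138 with an estimated correlation; without low-dose Sod2 KO replicate 30 the hypoxia and glycolysis list had adjusted p 0.0601. Without that array the ribosomal protein list passed, with mean 0.083 and adjusted p 0.0118.

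The other lists did not pass the camera set test at the low dose; with fry, endoplasmic reticulum chaperones (adjusted p 0.0333), heat shock proteins (0.00707), amyloid and tau genes (0.00231) and oligodendrocyte precursor markers (0.00571) passed, all lower on average in KO. Endoplasmic reticulum chaperones had 0 higher and 6 lower of 17 (0 and 7 adjusted over the list alone), heat shock proteins 2 and 4 of 10 (2 and 4), and amyloid and tau genes 1 and 6 of 26 (1 and 6). Ribosomal proteins had 1 and 0 of 48 (1 and 0), GABA signalling 1 and 1 of 12 (2 and 2), and myelin markers 1 and 5 of 20 (1 and 5). Oligodendrocyte precursor markers had 1 and 2 of 8 (1 and 3), astrocyte markers 3 and 3 of 17 (3 and 3), and endothelial markers 1 and 1 of 16 (0 and 1). Erythroid markers had 0 and 2 of 6 (0 and 2), region markers 1 and 0 of 12 (1 and 0), and sex-linked genes 0 and 0 of 5 (0 and 0). In 3 lists mean and median differed in sign. Metallothioneins (0 and 0 of 3; 0 and 0 adjusted over the list alone) had mean -0.031 and median 0.10, with the set test upward. P53 targets (2 and 2 of 16; 2 and 2) had 0.037 and -0.018, with the test upward. Choroid plexus markers (1 and 2 of 14; 1 and 2) had 0.002 and -0.036, with the test downward.

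At the high dose, the difference between Sod2 KO and wild type was smaller. Nupr1 was 2.95-fold higher in KO (log2 1.56 ± 0.22) and Enpp5, a transmembrane nucleotide pyrophosphatase family member, 3.18-fold higher (log2 1.67 ± 0.35). Enpp5 was higher in KO on all 6 chips with both groups, by 1.01 to 2.63. It also varied widely without the mutation: low-dose minus untreated wild type ran from -2.07 to 1.99 on single chips. Cyp51, a cholesterol synthesis enzyme, was 1.67-fold lower (log2 -0.74 ± 0.14), and Tph2, the neuronal tryptophan hydroxylase, 1.42-fold lower (log2 -0.51 ± 0.072). In all, 75 genes changed, 44 higher and 31 lower in KO, 2 by more than 2-fold. With marker means of 4 cell types as covariates, 242 passed, 73 of them among the 75. Hmox1 lay at the limit for dim probes in both groups, so no difference could be read for it.

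Cholesterol synthesis was the list that passed at the high dose with both kinds of correlation. Of 18 measured genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone; mean -0.20, adjusted p 1.49e-07), and adjusted p = 0.00376 with an estimated correlation. With Cyp51, the sterol enzymes Hmgcs1 and Sc5d changed by -0.53 ± 0.12 and -0.35 ± 0.082. The list mean was lower in KO on all 6 chips with both groups, with differences between -0.35 and -0.13. Of 17 glucocorticoid response genes, 5 rose and 0 fell (10 and 0 adjusted over the list alone; mean 0.34, adjusted p 6.42e-12), and adjusted p = 0.0537 with an estimated correlation. The members were Tsc22d3 at 0.76 ± 0.20, the sulfotransferase Sult1a1 at 0.66 ± 0.16, the receptor co-chaperone Fkbp5 at 0.64 ± 0.14, the lipid droplet protein Plin4 at 0.63 ± 0.16, and the NF-kappaB inhibitor Nfkbia at 0.58 ± 0.13. Of 29 ATF4 targets, 2 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p 8.1e-07, and adjusted p = 0.0537 with an estimated correlation). These were Nupr1 and Atf5, the latter at 0.71 ± 0.17. The calls for Atf5 and Sult1a1 ended with the chip as a fixed block.

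Other lists with changed members at the high dose had 1 or 2 each. With the chip as a fixed block the calls below for Ifitm3, Prdx4, Psmb1, Laptm5 and Gadd45g ended, and so did the microglia set test. Fatty acid oxidation had 2 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p 5.93e-06, and adjusted p = 0.14 with an estimated correlation), with the acyl-CoA dehydrogenase Acadvl at 0.32 ± 0.081. Interferon and inflammation had 2 and 0 (5 and 0 adjusted over the list alone; adjusted p 5.5e-06, and adjusted p = 0.152 with an estimated correlation), Nfkbia and the antiviral membrane protein Ifitm3 at 0.72 ± 0.18. Antioxidant enzymes had 1 and 0 (1 and 0 adjusted over the list alone; adjusted p 0.0013, and adjusted p = 0.14 with an estimated correlation), the peroxiredoxin Prdx4 at 0.30 ± 0.075. The proteasome subunit Psmb1 changed by 0.30 ± 0.074 (list 1 and 0; 1 and 0 adjusted over the list alone; adjusted p 0.01, and adjusted p = 0.302 with an estimated correlation). The microglial lysosomal protein Laptm5 changed by -0.43 ± 0.11 (list 0 and 1; 0 and 1 adjusted over the list alone; adjusted p 0.0358, and adjusted p = 0.733 with an estimated correlation). The stress gene Gadd45g, a p53 list member, changed by 0.58 ± 0.14 (list 1 and 0; 2 and 0 adjusted over the list alone; adjusted p 0.211). None of the 23 NRF2 targets changed in limma's test over all genes (3 higher and 1 lower adjusted over the list alone; adjusted p 0.0225, and adjusted p = 0.321 with an estimated correlation). Ribosomal proteins had no changed member, a mean of 0.12 and adjusted p 5.69e-08, and adjusted p = 0.226 with an estimated correlation. Complex I, the mitochondrial ribosome and region markers also passed as sets without a changed member, with means 0.087, 0.058 and 0.10 and adjusted p 0.0102, 0.00171 and 0.0225. For these the adjusted p = 0.733, 0.609 and 0.226 with an estimated correlation. High-dose wild type replicate 13 lay far below its group for complex I, the mitochondrial ribosome and ribosomal proteins, at -0.48, -0.25 and -0.36. Replicate 11 lay far below it for region markers, at -0.26. These single arrays enlarge the differences. Mean, median and test differed in sign for the TCA cycle, synaptic vesicle, neuron, choroid plexus and sex-linked lists, none of which passed. The neuron marker mean differed by 0.01 ± 0.052 (SE), permutation p 0.85 and adjusted p 0.98, and the microglia marker mean by -0.16 ± 0.069, permutation p 0.035 and adjusted p 0.156.

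Rbm3, Agt and Etnppl, which breaks down phosphoethanolamine, were also higher in KO at the high dose, by 0.77 ± 0.13, 0.75 ± 0.11 and 0.86 ± 0.19. Etnppl and Plin4 in wild type lay near the limit for dim probes, so their changes are lower bounds. Fcrls changed by -0.72 ± 0.15, Tlcd4 by -0.54 ± 0.10, the cytoskeletal protein Epb41l1 by -0.45 ± 0.12, Igdcc4 by -0.45 ± 0.11, and the splicing factor Srsf1 by -0.45 ± 0.093. Dimmer probes gave 0.31 for Gadd45g and near 0 for the dimmest of 3 Epb41l1 probes. The count at the high dose rested on single arrays: it was 30 without KO replicate 1, 41 without replicate 5, 39 without replicate 8, 47 without wild type replicate 13 and 45 without replicate 15. Without KO replicate 1 the calls ended for Etnppl, Tsc22d3, Ifitm3, Hmgcs1, Epb41l1, Igdcc4, Sult1a1, Plin4, Sc5d, Atf5, Acadvl, Prdx4, Psmb1, Laptm5 and Gadd45g, with adjusted p from 0.0623 for Etnppl to 0.157 for Tsc22d3, while the cholesterol list kept adjusted p = 0.00286 with an estimated correlation.

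Within Sod2 KO, the high dose came with much lower stress response RNA than the low dose. Synaptic, neuron, myelin, region and erythroid markers were higher on average, while astrocyte and microglia markers were slightly lower. The synaptic vesicle, postsynaptic and neuron lists had adjusted p = 0.0613, 0.0858 and 0.0883 with an estimated correlation. Hmox1 was at least 5.4-fold lower (log2 -2.43 ± 0.23), Ephx1 2.61-fold lower (log2 -1.39 ± 0.10) and Cdo1 2.68-fold lower (log2 -1.42 ± 0.13). Igfbp5 was 2.49-fold higher (log2 1.32 ± 0.19). In all, 1902 genes changed, 893 higher and 1009 lower at the high dose, 13 by more than 2-fold. With marker means of 4 cell types as covariates, 858 passed, 668 of them among the 1902.

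Of 23 NRF2 targets, 0 rose and 12 fell at the high dose (0 and 13 adjusted over the list alone; mean -0.43, adjusted p 6.19e-11), with Gstm1 at -0.90 ± 0.17 and Gclm at -0.89 ± 0.076. Of 29 ATF4 targets, 0 rose and 14 fell (1 and 16 adjusted over the list alone; mean -0.27, adjusted p 3.36e-08). Of 20 fatty acid oxidation genes, 0 rose and 12 fell (1 and 12 adjusted over the list alone; mean -0.34, adjusted p 9.41e-09). Acadl changed by -0.78 ± 0.12, the electron transfer proteins Etfdh and Etfa by -0.68 ± 0.086 and -0.56 ± 0.10, and the hydratase Echs1 by -0.63 ± 0.085. Of 18 TCA cycle genes, 0 rose and 10 fell (0 and 11 adjusted over the list alone; mean -0.29, adjusted p 9.41e-09). Cs changed by -0.58 ± 0.10, Sdhb by -0.52 ± 0.076, and the pyruvate dehydrogenase subunits Pdha1 and Pdhb by -0.50 ± 0.095 and -0.42 ± 0.10. Iron and haem handling had 1 higher and 7 lower of 21 (1 and 9 adjusted over the list alone; adjusted p 0.00198), and mitochondrial chaperones 0 and 5 of 13 (0 and 5; adjusted p 6.26e-05). With an estimated correlation the adjusted p was 0.00276 for NRF2, 0.025 for ATF4, 0.0294 for fatty acid oxidation, 0.0294 for the TCA cycle, 0.0356 for iron and haem, and 0.025 for mitochondrial chaperones. Antioxidant enzymes had 0 higher and 6 lower (0 and 6 adjusted over the list alone; adjusted p 0.000837), and adjusted p = 0.0711 with an estimated correlation.

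Of 32 synaptic vesicle genes, 12 rose and 0 fell at the high dose in KO (22 and 0 adjusted over the list alone; mean 0.34, adjusted p 9.41e-09), and adjusted p = 0.0613 with an estimated correlation. The vesicle proteins Sv2b and Syn1 changed by 0.83 ± 0.27 and 0.60 ± 0.14, and the vesicular glutamate transporter Slc17a7 by 0.66 ± 0.23. The postsynaptic list had 9 higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p 4.01e-06, and adjusted p = 0.0858 with an estimated correlation), and neuron markers 8 and 0 (10 and 0 adjusted over the list alone; adjusted p 9.31e-06, and adjusted p = 0.0883 with an estimated correlation). The neuron marker mean differed by 0.33 ± 0.092 (SE), permutation p 0.0021 and adjusted p 0.0453, higher in 10 of 10 high-dose KO mice than the low-dose mean. The synaptic vesicle mean differed by 0.34 ± 0.093, permutation p 0.0026 and adjusted p 0.0453, and was higher on all 6 chips, with differences between 0.18 and 0.94. Mean, median and test differed in sign for complex I (mean -0.067, median 0.013), heat shock and glucocorticoid lists. Low-dose KO replicate 30 lay far below its group for complex I, at -0.62, which makes this mean difference smaller. Without that array complexes II, III and IV passed, with mean -0.15 and adjusted p 0.00368. Some markers outside the synapse also rose. The myelin list had mean 0.18 and adjusted p 0.026, and adjusted p = 0.487 with an estimated correlation. Low-dose KO replicate 25 lay far below its group for the myelin list, at -0.70, which enlarges this difference. The region marker list had mean 0.18 and adjusted p 0.0321, and adjusted p = 0.227 with an estimated correlation, and was higher on all 6 chips. The erythroid marker mean differed by 0.19 ± 0.053, permutation p 0.0034 and adjusted p 0.0453. The astrocyte and microglia means moved the other way, at -0.076 ± 0.065 and -0.094 ± 0.084 (permutation adjusted p 0.459 and 0.467). The endothelial and choroid plexus means differed by 0.050 ± 0.035 and 0.021 ± 0.041 (0.32 and 0.869).

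**Figure D3:**
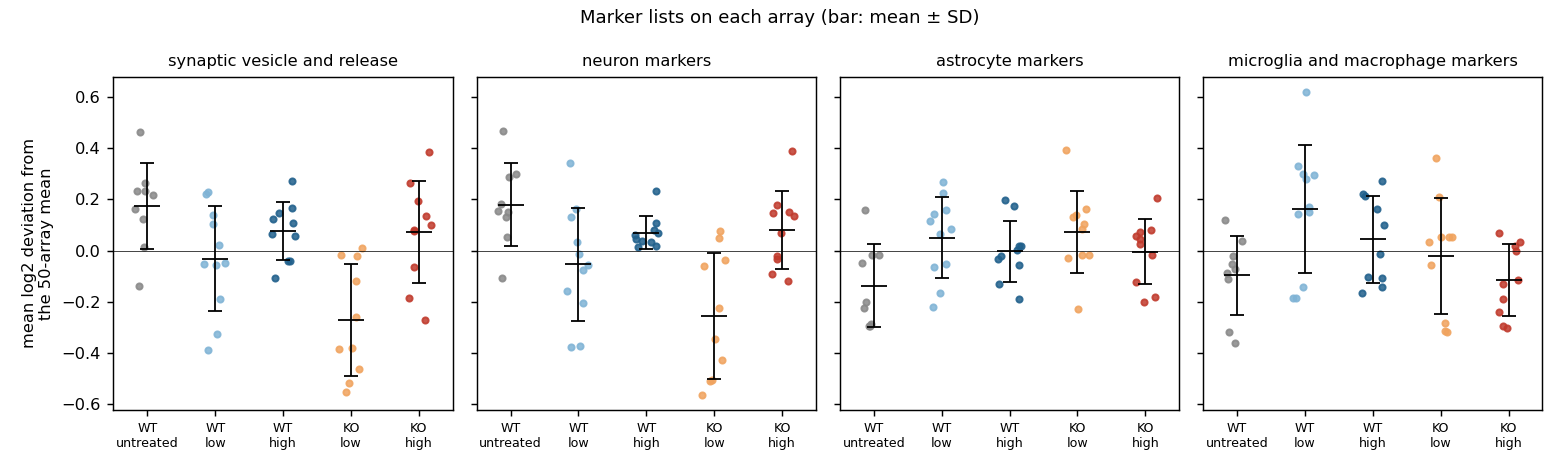
Mean log2 deviation of 4 lists from their 50-array mean, 1 point per array, with bars for mean and SD. Between high-dose and low-dose Sod2 KO the neuron marker mean differed by 0.33 ± 0.092 (SE) and the synaptic vesicle mean by 0.34 ± 0.093.

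Other genes named in the dose comparison within KO were higher at the high dose: the sodium channel genes Scn4b and Scn1a (1.02 ± 0.23 and 0.91 ± 0.28), the neuronal chemokine Cx3cl1 (1.00 ± 0.31), Prr18 (0.98 ± 0.16), Mmp17 (0.95 ± 0.21), the synaptic adhesion protein Clstn3 (0.92 ± 0.30) and Celsr2 (0.90 ± 0.31). The growth factor binding protein Igfbp2 changed by -1.55 ± 0.14, Ccdc80 by -1.30 ± 0.10, Mat2a by -1.29 ± 0.14, and the endothelin receptor Ednrb by -1.26 ± 0.13. Sod2 differed by -0.10 ± 0.09, adjusted p 0.524. Dimmer probes gave smaller changes for Mat2a (-0.85, -0.57 and -0.64), Acadl (-0.35), Gstm1 (-0.14), Pdhb (-0.060), Clstn3 (0.025) and, for the dimmest probe, Ednrb (-0.63) and Sdhb (near 0). Calls for Celsr2 and Slc17a7 ended without KO replicate 1 (adjusted p 0.0588 and 0.0574), and those for Celsr2, Sv2b and Slc17a7 without low-dose KO replicate 30 (0.0805, 0.0557 and 0.0956).

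The dose contrast in KO shares its low-dose KO arrays with the low-dose genotype contrast, which alone makes their changes run in opposite directions. Of the 2307 genes called between genotypes at the low dose, 728 were higher in KO and then lower at the high dose, and 546 were lower and then higher, against 97.5 and 92.7 for independent lists. The correlation across genes was -0.822, against -0.510 in simulated data with no effect. With the low-dose KO arrays split into separate sets for each contrast, it was -0.647 on average over 100 splits. Genes are not independent replicates.

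Whether the genotype change differed between doses was tested directly. The difference passed for 334 genes, 224 with a positive value for low minus high dose and 110 with a negative one. Among the largest values were Hmox1 at 2.37 ± 0.33, which is inexact since its signal in 3 of the 4 groups lay at the limit for dim probes, Ephx1 at 1.36 ± 0.14, Igfbp2 at 1.35 ± 0.20, Cdo1 at 1.34 ± 0.19 and Ccdc80 at 1.29 ± 0.13. Among the lowest were Igfbp5 at -1.24 ± 0.26, Pdzph1 at -0.95 ± 0.16, the myelin gene Opalin at -0.84 ± 0.21 and the ciliary transport gene Ift27 at -0.80 ± 0.16. Of 23 NRF2 targets 8 passed upward and 0 downward (9 and 0 adjusted over the list alone; mean 0.40, adjusted p 5.28e-11, and 0.00264 with an estimated correlation). TCA cycle, ATF4, fatty acid oxidation, mitochondrial chaperone, iron and haem, and hypoxia and glycolysis lists also passed with an estimated correlation, at adjusted p 0.0282, 0.0236, 0.0265, 0.0267, 0.0284 and 0.0263. The synaptic vesicle list had mean -0.23 and adjusted p 5.17e-05, and adjusted p = 0.225 with an estimated correlation. Nupr1 had a difference of 0.90 with adjusted p 0.101, Cyp51 -0.081 with 0.895, and Enpp5 -0.48 with 0.705.

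Averaged over both doses, 1960 genes differed between genotypes, 905 higher and 1055 lower in KO. Among the highest were Nupr1 at 2.02 ± 0.15, Enpp5 at 1.43 ± 0.24, Hmox1 at 1.34 ± 0.16 (inexact for the same reason), Agt at 1.22 ± 0.079 and Atf5 at 1.22 ± 0.12. Enpp5 also varied widely between wild type groups on single chips, as given above. The lowest were Arc at -1.22 ± 0.21, Fcrls at -0.88 ± 0.10, Pdzph1 at -0.88 ± 0.082, Igfbp5 at -0.88 ± 0.13 and Cyp51 at -0.78 ± 0.10. Over these genes the slope of the high-dose on the low-dose change was 0.357 (permutation p 0.0004, median of permuted slopes 0.917). The change was larger at the low dose for 1734 genes (88.5%, permutation p 0.0019).

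The direction of the genotype change was largely shared between the doses. Of the 75 genes called at the high dose, 72 had the same sign at the low dose, and of the 2307 called at the low dose, 1845 (80.0%) had the same sign at the high dose. Genes higher in KO at both doses numbered 33 against 4.25 for independent lists, and genes lower at both numbered 25 against 3.22. No gene was called in opposite directions. Across all genes, Pearson r was 0.522 and Spearman rho 0.370; these contrasts share no arrays, but genes are not independent replicates.

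**Figure D4:**
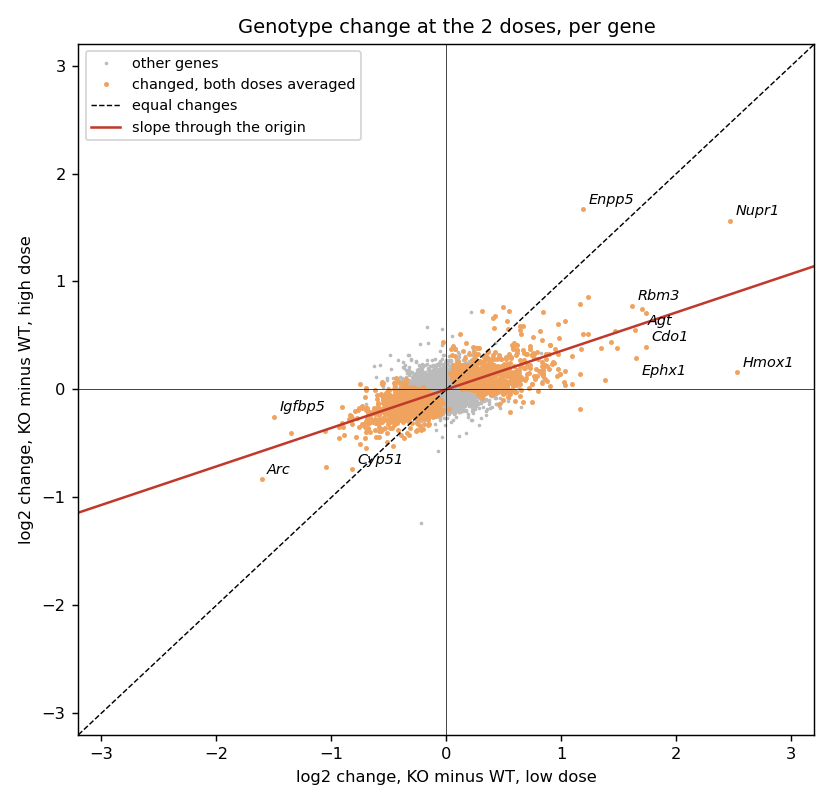
Log2 change of Sod2 KO against wild type for each of 11510 genes at the low dose (horizontal axis) and the high dose (vertical axis); orange points are the 1960 genes called in the averaged contrast. Their slope of 0.357 lies below the dashed line of equal changes, with Nupr1 at 2.47 and 1.56.

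In wild type mice few or no single genes passed between treatments, though several marker lists shifted with the preset correlation. The high dose against the low dose gave 0 changed genes in limma and 510 at an unadjusted p below 0.05. Chance alone puts on average a share of 0.05 of the 11510 genes below that level, so 510 is no excess. The smallest p belonged to the kinase Dclk2 (0.30 ± 0.073), Fam163b (-0.16 ± 0.041) and the Golgi protein Golm1 (-0.31 ± 0.081), which did not pass (adjusted p 0.844). The lists that passed were microglia markers (mean -0.12, adjusted p 4.33e-05), neuron markers (0.12, 0.00127), synaptic vesicle genes (0.11, 0.00163), postsynaptic genes (0.078, 0.0141) and the mitochondrial ribosome (-0.053, 0.00163). For the first 2 the adjusted p = 0.833 with an estimated correlation, and for the other 3 it was 0.858. The high dose against no treatment gave 0 changed genes in limma and 728 at an unadjusted p below 0.05, with Colgalt1 (-0.32 ± 0.084), the transcription factor Klf5 (-0.15 ± 0.041) and the liver-type methionine adenosyltransferase Mat1a (-0.14 ± 0.038) nearest to passing (adjusted p 0.766). The lists that passed there were microglia markers (mean 0.14, adjusted p 0.000693), astrocyte markers (0.13, 0.00609), postsynaptic genes (-0.10, 0.0188), fatty acid oxidation (0.10, 0.0181) and iron and haem handling (0.051, 0.0201). With an estimated correlation none passed, with adjusted p = 0.583 for iron and haem, 0.711 for astrocytes and 0.826 for the other 3.

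The low dose against no treatment in wild type gave 3 changed genes in limma and 1540 at an unadjusted p below 0.05. The other wild type comparisons had 510 and 728 at that level. Laptm5 was higher by 0.54 ± 0.11 and Syngr2, a vesicle protein of many cell types, by 0.31 ± 0.06, while Fam171a1 was at -0.27 ± 0.054. Of 20 microglia markers 1 rose and 0 fell (12 and 0 adjusted over the list alone; mean 0.26, adjusted p 7.36e-11), and adjusted p = 0.276 with an estimated correlation. Neuron markers had mean -0.23 and adjusted p 1.53e-05, and adjusted p = 0.276 with an estimated correlation. Astrocyte markers had mean 0.19 and adjusted p 0.000805, and adjusted p = 0.306 with an estimated correlation. Synaptic vesicle (-0.21, adjusted p 4.56e-05), postsynaptic (-0.18, 1.53e-05), endoplasmic reticulum chaperone (-0.13, 0.00255), ribosomal protein (-0.059, 0.0314), fatty acid oxidation (0.10, 0.0314), and iron and haem lists (0.067, 0.0314) also passed. In that order the adjusted p = 0.35, 0.276, 0.434, 0.78, 0.676 and 0.276 with an estimated correlation. The exact permutation p of the marker means was 0.0145 for microglia, 0.0173 for neurons and 0.0195 for astrocytes, with adjusted p 0.111 for each. For synaptic vesicle genes and myelin markers it was 0.0266 and 0.0432, with adjusted p 0.133 and 0.173. For endothelial, choroid plexus and erythroid markers it was 0.406, 0.264 and 0.391. The 3 calls rested on single arrays: 0 genes passed without any one of low-dose replicates 32, 34, 35, 38 and 40 or untreated replicates 43, 44, 46, 48, 49, 50 and 51, while 47 passed without low-dose replicate 41 and 5 without replicate 42. With the chip as a fixed block, or with only these groups in the fit, 0 passed.

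Both KO groups were also set against untreated wild type, where genotype and treatment differ together and cannot be separated. Low-dose KO differed in 3357 genes, 1526 higher and 1831 lower, 84 by more than 2-fold. Hmox1, Nupr1, Atf5, Rbm3 and Mat2a were among the highest, at 2.54 ± 0.24 (a lower bound), 2.34 ± 0.23, 1.80 ± 0.18, 1.72 ± 0.13 and 1.68 ± 0.15. Cx3cl1, Arc, Itpr1, Igfbp5 and the axon guidance gene Sema7a were lowest, at -1.46 ± 0.31, -1.38 ± 0.31, -1.37 ± 0.15, -1.34 ± 0.19 and -1.32 ± 0.18. Of 32 synaptic vesicle genes 0 rose and 20 fell (0 and 21 adjusted over the list alone; mean -0.44, adjusted p 8.99e-08), and adjusted p = 0.0769 with an estimated correlation. Of 20 neuron markers 0 rose and 15 fell (0 and 15 adjusted over the list alone; mean -0.43, adjusted p 7.25e-06), and adjusted p = 0.0939 with an estimated correlation. With marker means of 4 cell types as covariates, 982 genes passed, 831 of them among the 3357.

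High-dose KO differed from untreated wild type in 141 genes, 74 higher and 67 lower, 5 by more than 2-fold. With marker means of 4 cell types as covariates, 77 genes passed, 58 of them among the 141. Nupr1, Enpp5, the small heat shock protein Hspb6 and Ifitm3 were highest, at 1.53 ± 0.23, 1.41 ± 0.36, 1.13 ± 0.18 and 1.04 ± 0.19. Sphkap, the neuronal gene Enc1, Itpr1 and the sterol enzyme Sqle were among the lowest, at -0.63 ± 0.12, -0.60 ± 0.14, -0.57 ± 0.15 and -0.52 ± 0.13. Fatty acid oxidation had 4 of 20 higher and 0 lower (11 and 0 adjusted over the list alone), with adjusted p 8.51e-10, and 0.0327 with an estimated correlation. Cholesterol synthesis had 0 higher and 1 lower (0 and 7 adjusted over the list alone), with adjusted p 3.12e-05, and 0.0327 with an estimated correlation. The count moved with single arrays. It was 43 without KO replicate 1, 70 without replicate 3, 44 without replicate 5, 276 without replicate 7 and 55 without replicate 8. It was 89, 83, 93, 222, 70, 58 and 79 without untreated replicates 43, 44, 46, 47, 48, 49 and 51. Without KO replicate 1 the calls for Enpp5, Enc1, Itpr1 and Sqle ended, with adjusted p from 0.0784 for Enpp5 and Enc1 to 0.101 for Itpr1. Astrocyte markers passed as a list, higher in KO, but not without KO replicate 1 (mean 0.11, adjusted p 0.052). Neuron markers passed only without it (mean -0.11, adjusted p 0.0429). Without it the adjusted p = 0.497 and 0.534 with an estimated correlation.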

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

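The tests chosen after the result was seen were the chip block for the dose difference (a planned fit, put to this use later), both tests of the synaptic pattern, and the count of higher markers for the microglia pattern, while single arrays left out and cell type covariates were added after the data were seen but before their results for the dose difference. The outlying values below come from 432 tests of a group of 9 or 10 arrays, where chance alone gives about 1 in 20; the low-dose wild type group of 11 was not tested.

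The genotype change was larger at the low dose than at the high dose, with 334 genes differing in a direct test. With the chip as a block 285 of these calls stayed, with the sex-linked signal as a covariate 315 stayed, and leaving out any 1 array left at least 273 in total. With neuron, astrocyte, microglia and myelin marker means as covariates 294 passed, and 202 of the 334 stayed. Other cell types were not in that fit, and marker means from the same arrays measure cell content only in part. Cell type content therefore stays open for the calls that ended, and in part for those that stayed. Each of these argues against that factor as the whole cause, for cell type content only as far as these marker means measure it. The dose itself is the candidate explanation that the design names. Litter, preparation day and the age of each mouse within 17 to 21 days are not given in the labels. These stay open, here and for the patterns below, and no untreated KO shows the change without treatment.

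Synaptic vesicle and neuron marker lists were lower on average in Sod2 KO than in wild type at the low dose, with adjusted p = 0.21 and 0.319 with an estimated correlation, and the means did not pass by permutation (adjusted p 0.111 and 0.18). With the chip as a block and the sex-linked signal as a covariate together, the synaptic vesicle mean stayed at -0.26 ± 0.088, or -3.02 standard errors, which argues against chip and sex as the whole cause. A smaller neuronal share of the preparation would raise the markers of all other cell types. The differences were -1.75 standard errors for microglia, -1.55 for myelin, -0.502 for endothelium and 0.312 for astrocytes, and, outside the test, -1.86 for erythroid and 0.047 for choroid plexus markers; none rose clearly, but none fell past 2 standard errors, so a change within nerve terminals and a lower neuronal share cannot be told apart.

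Microglia markers were higher on average in low-dose than in untreated wild type, with 1 of 20 called and adjusted p = 0.276 with an estimated correlation, while neuron markers moved by -0.23 and astrocyte markers by 0.19. Of the 20 measured markers 19 had a higher mean, but the list was picked for its higher mean, so this count says nothing on whether the preparation held more microglial material. With the chip as a block the difference was 0.259, against 0.258 without, which argues against the chip. The exact permutation p was 0.0145, but the list stood out among 37, and over 40 comparisons the adjusted p was 0.111, so a chance difference between animals stays open. An effect of the treatment was not tested apart from these.

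For each comparison, 100 splits of the arrays into groups of the same sizes were fitted, the real one included, and the number with as many changed genes was counted. The count was 1 for the low-dose genotype comparison (2307 genes, highest other split 1098), 1 for the high-dose one (75, highest other 3), and 1 for the doses within KO (1902, highest other 1782). The split with 1098 kept 17 of 21 arrays in their own group, and the split with 1782 kept 2 of 20, the mirror of one that keeps 18. It was 1 for the difference between doses (334, highest other 79), 1 for the averaged genotype comparison (1960, highest other 0), 1 for low-dose KO against untreated wild type (3357, highest other 403), and 1 for high-dose KO against it (141, highest other 6). In these comparisons no other split gave as many genes, which argues against chance as their source. With 100 splits the smallest share that can be seen is 1 in 100, so chance is not excluded. Chance stays open for the low dose against no treatment in wild type, with a count of 2 (3 genes, highest other 7), since another split gave more genes and leaving out single arrays ended the calls. It was 100 for the high against the low dose (0, highest other 10) and for the high dose against no treatment (0, highest other 1) in wild type; with 0 genes every split gives as many, so these counts say nothing about chance.

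Single arrays lay far from the rest of their group in 39 tests, 7 of them for high-dose KO replicate 1, 6 each for low-dose KO replicate 30 and untreated replicate 47, and 4 each for high-dose wild type replicate 13 and untreated replicate 49. High-dose KO replicate 1 had log2 signals of 8.35 for Agt, 6.56 for Arc, 8.54 for Angptl4, 7.07 for Tlcd4, 7.95 for Srsf1 and 8.25 for Nfkbia, and a glucocorticoid list mean of 0.94 from the 50-array mean. Low-dose KO replicate 30 had 10.10 for Echs1 and 11.54 for Etfa, and list means of -0.62 for complex I, -0.44 for complexes II, III and IV, -0.38 for ATP synthase and -0.61 for ribosomal proteins. Untreated replicate 47 had 9.40 for Srsf1, 9.51 for Clstn3, 10.32 for Pdha1, 8.23 for Sv2b, 6.72 for Colgalt1 and 7.56 for Sema7a. High-dose wild type replicate 13 had 8.46 for Psmb1, and list means of -0.48 for complex I, -0.25 for the mitochondrial ribosome and -0.36 for ribosomal proteins. Untreated replicate 49 had list means of -0.26 for complex I, -0.29 for complexes II, III and IV, -0.24 for ATP synthase and -0.22 for antioxidant enzymes.

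The other arrays had 1 or 2 such values each. In high-dose KO these were Eif4ebp1 at 8.08 and the mitochondrial ribosome mean at 0.19 in replicate 5, and the endoplasmic reticulum chaperone mean at 0.33 in replicate 7. In low-dose KO they were Sdhb at 9.12 in replicate 31, Ifitm3 at 9.47 in replicate 24, Srsf1 at 9.22 in replicate 28, and the myelin mean at -0.70 in replicate 25. In high-dose wild type they were Nupr1 at 9.09 in replicate 19, Mmp17 at 8.01 in replicate 16, the neuron mean at 0.23 in replicate 20, and the region marker mean at -0.26 in replicate 11. In untreated wild type it was Nfkbia at 6.19 in replicate 46.

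Of 81 named genes, 29 had a genotype change that differed between the doses, given here as the low-dose minus the high-dose log2 change. Some genes were named for large changes in this same test. Many others were named for changes in the low-dose genotype contrast or the dose contrast in KO, which share arrays with it. The number is therefore set in large part by the choice and cannot be compared with that over all genes. Over all 11510 genes 334 passed. The Hmox1 value is inexact, since its signal lay at the limit for dim probes in 3 of the 4 groups. Among stress and detoxification genes these were Hmox1 2.37, Ephx1 1.36, Gstm1 0.93, Gclm 0.78, Cat 0.66, Atf5 1.03 and Slc7a5 0.98. Among fuel and mitochondrial genes they were Acadl 0.84, Acadvl 0.43, Etfdh 0.69, Etfa 0.49, Echs1 0.53, Cs 0.55, Sdhb 0.46, Idh3g 0.37, Pdha1 0.51 and Pdhb 0.48. The others with a positive value were Cdo1 1.34, Agt 0.96, Mat2a 1.09, Rbm3 0.84, Igfbp2 1.35, Ccdc80 1.29 and Ednrb 1.05. Those with a negative value were Igfbp5 -1.24, Pdzph1 -0.95, Gadd45g -0.75, Opalin -0.84 and Ift27 -0.80.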

How the results depend on the processing

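The 70th percentile filter, leaving out arrays, and cell type covariates were chosen after seeing the data. The planned strict detection filter could not be run, as the table holds no detection p-values. No result reversed. Array medians of raw signal lie near the lower end of the scale, which limits what dim genes can show. Counts of changed genes within 1.5 times the main count are not listed here, with 2 exceptions. These are the ranges over single arrays left out and the low-dose genotype count with cell type covariates. That count was 1707, and only 1367 of the 2307 main calls were among them.

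With cell type markers as covariates, 242 genes changed between genotypes at the high dose (75 before), 858 between doses in KO (1902), 0 for the low dose against no treatment in wild type (3), 982 for low-dose KO against untreated wild type (3357) and 77 for high-dose KO against it (141). Not all of these were main calls: in that order 73, 668, 0, 831 and 58 were. Without the chip of 2 arrays the counts were 47 for genotype at the high dose, 0 for the low dose against no treatment and 88 for high-dose KO against untreated. With array weights they were 7 and 248 for the latter 2, and with only the groups compared 0 and 93. With the chip as a fixed block the low dose against no treatment gave 0. Leaving out 1 array gave 30 to 105 genes for genotype at the high dose, 0 to 47 for the low dose against no treatment and 43 to 276 for high-dose KO against untreated. For the other comparisons it gave 2090 to 2427 (genotype, low dose), 1597 to 2080 (doses in KO), 273 to 427 (difference between doses), 1788 to 2058 (averaged genotype) and 3018 to 3408 (low-dose KO against untreated). The cause was not tested.

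Calls of single genes ended most often for genotype at the high dose. With the chip as a fixed block they ended there for Ifitm3, Epb41l1, Sult1a1, Atf5, Prdx4, Psmb1, Laptm5 and Gadd45g, and with the sex-linked covariate for Tsc22d3, Ifitm3, Epb41l1, Sult1a1, Plin4, Sc5d, Atf5, Acadvl, Prdx4 and Psmb1. With only the groups compared they ended for Tsc22d3, Epb41l1, Srsf1, Fkbp5, Plin4, Atf5, Nfkbia and Gadd45g, and with no filter for Tsc22d3, Ifitm3, Epb41l1, Sult1a1, Plin4, Acadvl, Prdx4, Psmb1 and Laptm5. With the authors' values they ended for Hmgcs1, Epb41l1 and Laptm5, and without background correction for Plin4. Between doses in KO, calls ended for Cx3cl1, Clstn3, Scn1a, Celsr2 and Slc17a7 with only the groups compared, and for Celsr2 and Slc17a7 with no filter. For the low dose against no treatment, Laptm5, Syngr2 and Fam171a1 ended with the chip block and with only the groups compared, and Fam171a1 with the sex-linked covariate. For high-dose KO against untreated, Itpr1 ended with the chip block, the authors' values, no filter and only the groups compared, Sqle with the chip block and only the groups compared, and Enc1 with the latter. Named calls for genotype at the low dose all stayed under these alternatives, which did not include the cell type covariates. Set tests ended with the chip as a fixed block for microglia markers (genotype, high dose), immediate early genes (difference between doses), iron-sulfur assembly (averaged genotype), the mitochondrial ribosome (high-dose KO against untreated), and complexes II, III and IV, iron-sulfur assembly, amyloid and tau, and myelin lists (low-dose KO against untreated). The same block brought 7 other list calls past the threshold.

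Fewer lists passed with an estimated correlation: 6 (22 before) for genotype at the low dose, 1 (13) at the high dose, 6 (20) between doses in KO, 7 (14) for the difference between doses, 6 (22) for averaged genotype, 7 (24) for low-dose KO against untreated and 2 (14) for high-dose KO against it. In wild type it was 0 (5) for high against low dose, 0 (9) for low dose against no treatment and 0 (5) for high dose against no treatment. With fry, 6 passed for genotype at the high dose, 8 for high-dose KO against untreated, 1 for the low dose against no treatment, and 0 for each of the other wild type comparisons; over all comparisons fry ended 48 list calls and added 15. The preset correlation of 0.01 is below most estimates. The slope of the high-dose on the low-dose change was 0.366 with the chip as a block and 0.361 with the authors' values.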

Other observations

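No test in this part was chosen to explain a result. The first principal component held 28.8% of the variance, and group accounted for 0.588 of it and chip for 0.0576. The fourth held 5.62%, with chip at 0.650. The closest 2 arrays were untreated replicates 43 and 44, with a correlation of 0.994.

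The labels give no sex. The Y-linked gene Ddx3y split the arrays at a gap from 6.34 to 7.50 log2, with 29 arrays above it: 6 in low-dose KO, 6 in low-dose wild type, 7 in high-dose KO, 4 in high-dose wild type and 6 in untreated wild type. With group means removed, the correlation between arrays on the same chip was 0.0199 on average over genes, and array weights ranged from 0.460 to 1.69.

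In simulated data with independent genes, 31.3% of changes of 0.25 log2 in the difference between doses were recovered. For changes of 0.5 log2 it was 82.1%, so small differences between doses may often have been missed.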
